A study of Mus musculus with 6 samples.

How the data were processed

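RNA was measured in 6 libraries labelled as BMOL, a mouse liver progenitor cell line, of which 3 were labelled vector control and 3 TXNIP overexpression. Per the labels' protocols, RNA was taken up in Trizol and libraries were made with the Lexogen QuantSeq kit, which primes at the poly(A) tail and reads the 3' end of each messenger RNA. Per the series' design text, sequencing was single-end with 75 cycles on a NextSeq 550. The submitters' processing notes name Bowtie2, bedtools and the mouse build mm10. Their versions and settings, the gene annotation, the use of strand and the handling of duplicate reads are not given in the sources used here.

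The deposited files hold raw read counts per gene symbol, as whole numbers, with 1 file per library. Each lists 23282 entries with 23238 distinct symbols, and 35 symbols stood on more than 1 entry (79 entries). These entries were kept apart. Totals ranged from 8725624 to 15119775 counts. The 45S ribosomal RNA entry Rn45s held 9.24% ± 0.344 of the counts in the controls and 8.79% ± 0.840 in the other group (SD, n = 3 each). It was kept, and an alternative without it was run. Messenger RNAs of the mitochondrial genome had no entry in the files. Because no molecular identifiers are described, every counting interval and every floor covers counting error only.

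Genes were filtered with edgeR's filterByExpr at its defaults, which left 12088 genes. The deposited counts were scaled by TMM factors and tested with edgeR's quasi-likelihood test (version 4.0.16, R 4.3.3), with robust dispersions and the group as the only term. The test was two-sided, with Benjamini-Hochberg adjustment over the 12088 genes and a threshold of 0.05. Log2 fold changes are those of the libraries labelled TXNIP overexpression minus vector control, with their standard errors. Levels are CPM, the count scaled to a common library size with the TMM factors. Where every library of a group had 0 reads, the fold was computed against a floor of 3 reads over the group and written as a lower bound. With 1 to 3 reads in a group, the ratio of pooled counts is given with its exact 95% interval. Fitted fold changes of such genes depend on the prior count and are no bound. They are printed only where a left-out library moved them and no read count tells it.

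The genes named were set by a rule. It took Txnip and the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold with separated groups and a mean of at least 5 CPM. It also took the 4 members of each gene list with the smallest adjusted p, and 13 genes chosen for their link to TXNIP, the liver or the cell cycle. Besides Txnip, the rule took 144 genes, and the text prints 2 to 4 examples per list and not all of them. Other members of a list, and markers of other cell types, appear as examples of a count; they were picked after the result was seen. The 32 gene lists, the tests of genes and of these lists, the naming rule and all alternatives but 3 were fixed before the data were examined. The chromosome medians were computed after. Of the lists, 29 had at least 5 tested genes. Those were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the 29 lists. Camera with a correlation estimated per list, and fry, stood beside it. Gene positions are from the NCBI RefSeq annotation of GRCm38.p6, the assembly that mm10 represents, and 12044 of the tested genes (99.6%) could be placed.

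Chromosome medians used the 7234 placed genes with at least 10 CPM in both groups. Each median was taken relative to that of all 7234 genes and set against 10000 random gene sets of the same size, with Benjamini-Hochberg adjustment over 20 chromosomes. This permutation treats genes as exchangeable, and genes are not independent replicates.

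The scripts were tested on simulated counts drawn from the mean levels of the 3 controls and the library sizes of all 6 libraries. Over 11243 simulated genes, 50 were tested at each of 1.5-, 2- and 4-fold and 48 at 8-fold. The edgeR test recovered 12% of genes changed 1.5-fold, 56% of those changed 2-fold, 92% of those changed 4-fold and 95.8% of those changed 8-fold. Of its calls, 5.97% were of unchanged genes. Far more genes changed in the real comparison, so these shares need not hold for it. The alternatives were RLE and upper-quartile factors, library size alone, no filter, and a filter of 5 CPM in 3 libraries. DESeq2 1.42.0, limma-voom, limma-trend with prior counts of 2 and 0.5, and dispersions without robust estimation were also run. Other alternatives were a replicate block, each library left out in turn, an adjusted p of 0.01, a minimum fold of 1.5 and counts thinned to the smallest total. Those added after seeing the data were the removal of Rn45s, and the restriction to genes of at least 5 CPM in both groups for single genes and for lists. Plots were drawn with matplotlib 3.10.9.

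The labels do not say whether the 3 libraries of a group came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.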

Results

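Gene expression was measured by 3' messenger RNA sequencing in 6 libraries labelled as BMOL cells, a line of mouse liver progenitors. Of these, 3 were labelled as vector controls and 3 as overexpressing thioredoxin-interacting protein (TXNIP), an alpha-arrestin that binds thioredoxin and restrains glucose uptake. The control libraries held 8766820, 14125497 and 15119775 counts, and the others held 8725624, 10608637 and 11176554. Between 13257 and 13565 genes had at least 1 read in a control library, against 12488 to 12768 in the other group. Pearson correlations of log2 CPM across genes lay between 0.974 and 0.986 within groups and between 0.509 and 0.531 between groups. The first principal component carried 94.8% of the variance and separated the groups, and the second carried 1.82%. Within each group, replicate 1 stood apart from replicates 2 and 3, with a chi-square per degree of freedom over genes of 24.1 or more against 6.45 and 6.61 for the other pairs. No libraries were close enough to be the same library deposited again.

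The comparison sets the libraries labelled TXNIP overexpression against those labelled vector control. Txnip itself, at chromosome 3 from 96557957 to 96561857 (GRCm38.p6, protein-coding), had 38.3, 9.63 and 10.8 CPM in the controls and 217, 299 and 290 CPM in the libraries labelled TXNIP overexpression. Its mean rose from 19.6 ± 16.2 to 268 ± 44.9 CPM (SD, n = 3 each), a 13.7-fold difference. The log2 fold change was 3.82 ± 0.46 (SE), with an adjusted p of 2.8e-05 in edgeR's quasi-likelihood test. Without control replicate 1, which had the highest Txnip level of the controls, the log2 fold change was 4.71. Counts from the 3' end do not separate an introduced Txnip from the cell's own gene, and a construct without the gene's own 3' end need not be counted at all. The sequence of the construct is not given in the sources used here.

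The libraries labelled TXNIP overexpression carried abundant leukocyte transcripts, which were lower in the controls, and few or no reads of several epithelial genes that the controls expressed. Csf1r, the receptor for the macrophage growth factor CSF1, rose from 28.0 ± 3.0 to 1026 ± 141 CPM (SD, n = 3). Cd14, a co-receptor for lipopolysaccharide, rose from 53.4 ± 6.97 to 1425 ± 58.7 CPM. The keratin gene Krt18 stood at 516 ± 73.7 CPM in the controls and had 1 read over all 3 other libraries. The groups are named here by their labels only.

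**Figure D1:**
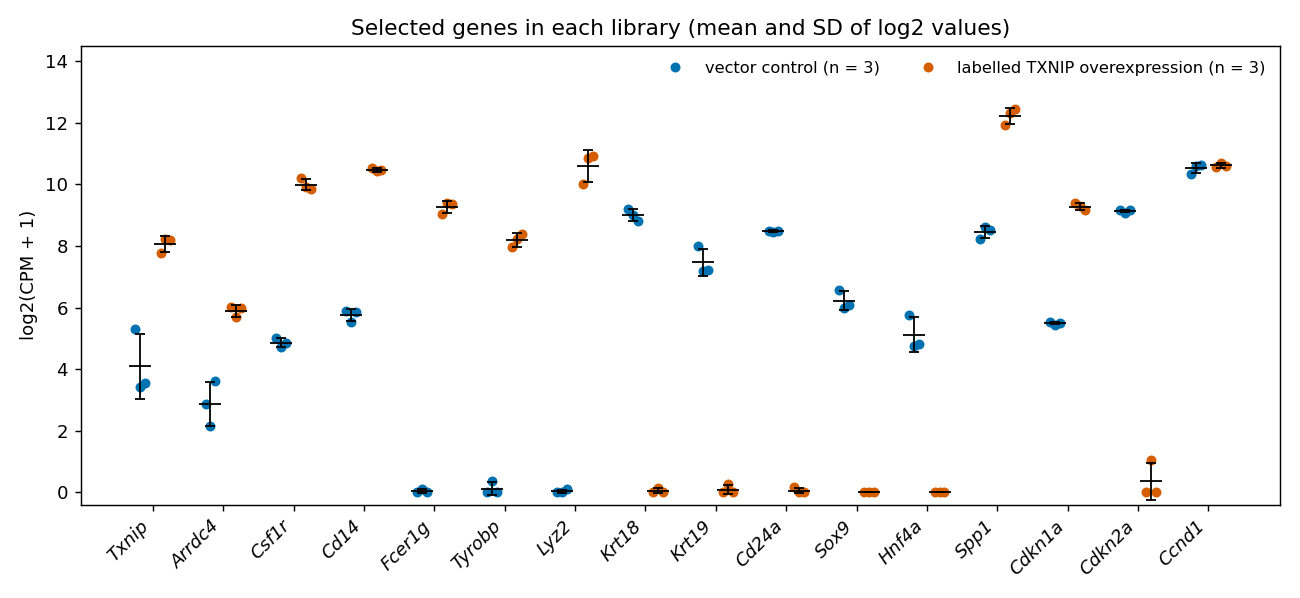
Level of selected genes in each library as log2(CPM + 1). Points are libraries (3 per group, blue for vector control and orange for those labelled TXNIP overexpression), and black bars give the mean and SD of the log2 values. Leukocyte genes such as Csf1r (28.0 and 1026 CPM) were high in the orange libraries, and epithelial genes such as Krt18 (516 CPM in controls) were near 0 there.

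Across the transcriptome, 7796 of 12088 tested genes (64.5%) changed in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3699 higher and 4097 lower in the libraries labelled TXNIP overexpression. Of these, 4915 differed by more than 2-fold, 2192 higher and 2723 lower. The groups did not overlap in 70.4% of tested genes, where chance gives 10%. Part of the difference was presence against absence. At 5 CPM or more in the libraries labelled TXNIP overexpression, 305 genes had at most 3 reads over the controls, and 611 genes showed the reverse. Among the 8425 genes with at least 5 CPM in both groups, 4982 changed, 2569 higher and 2413 lower.

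Among the 12 largest rises, the chemokine gene Ccl3 had no read in the controls and 1061 ± 70.2 CPM in the libraries labelled TXNIP overexpression, at least 13730.5-fold higher. The lipoprotein lipase gene Lpl (939 ± 75.7 CPM), the chemokine gene Ccl4 (590 ± 123), the cytokine gene Tnf (582 ± 131) and the scavenger receptor gene Msr1 (550 ± 87.6) also had no read in the controls. Each was at least 7115-fold higher. Rac2, Clec5a, Hcls1, Lilrb4a and the cathepsin gene Ctss had no control reads either and lay between 350 and 442 CPM. Ifitm3, an interferon-induced membrane protein gene, had 2 reads in the controls and 3507 ± 297 CPM in the other group. Lyz2, which encodes lysozyme, had 1 read in the controls, in replicate 3, and 1611 ± 503 CPM.

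Among the largest falls, all 12 genes had no read in the libraries labelled TXNIP overexpression. The neutrophil chemokine gene Cxcl5 had 409 ± 6.21 CPM in the controls and was at least 4057-fold lower. The matricellular gene Ctgf (364 ± 101 CPM), the thrombin receptor gene F2r (332 ± 23.5), the small heat shock gene Cryab (313 ± 18.4) and the transcription factor gene Sox11 (262 ± 26.4) were each at least 2599-fold lower. Cxcl1, Igf1r, Bicc1, the desmosomal cadherin gene Dsg2 and the mesothelin gene Msln lay between 163 and 217 CPM in the controls. Lgals2 and Tm4sf4 varied among the controls, with 379, 88.7 and 83.1 CPM and with 305, 100 and 107 CPM. Without control replicate 1 their fitted log2 fold changes moved from -14.03 to -13.00 and from -13.93 to -13.27.

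Markers of the bile duct lineage, to which liver progenitors are related, were mostly lower. Of 23 tested cholangiocyte and ductular markers, 20 fell, 1 rose and 2 did not pass, and the counts were the same adjusted over the list alone. Camera gave an adjusted p of 3.4e-17, and the call held with an estimated correlation (adjusted p = 0.0239 with an estimated correlation). Krt19 fell from 182 ± 60.4 CPM to 2 reads over the group, 2561-fold lower (exact 95% interval 709 to 21149). Cd24a fell from 358 ± 4.59 CPM to 1 read. The transcription factor gene Sox9 went from 74.7 ± 16.6 CPM to no read, at least 741-fold lower. The stray reads lay in 1 library each, those of Krt18 and Krt19 in replicate 2 and that of Cd24a in replicate 1 labelled TXNIP overexpression, and without it none were left. The member that rose was Spp1, which encodes osteopontin and is also expressed by macrophages, from 352 ± 45.6 to 4849 ± 840 CPM.

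Most hepatocyte markers had too few reads to test. Of 30 listed, 8 were tested, of which 6 fell, 1 rose and 1 did not pass. The counts were the same adjusted over the list alone. The camera call (adjusted p = 0.0434) was lost with an estimated correlation (adjusted p = 0.393 with an estimated correlation). It was also lost without control replicate 1 (adjusted p = 0.0687), control replicate 3 (0.0509) or replicate 1 labelled TXNIP overexpression (0.112). The liver transcription factor gene Hnf4a had 35.5 ± 15.6 CPM in the controls and no read in the other group. Rbp4, the retinol carrier gene, had 327 ± 38.7 CPM and then 2 reads. The fetal liver gene Afp rose from 11.1 ± 4.46 to 102 ± 8.39 CPM. Albumin (Alb) stood at 1.59 ± 1.92 and 0.646 ± 0.933 CPM and did not pass (edgeR adjusted p = 0.36).

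All 9 tested macrophage and leukocyte markers rose, out of 18 listed, with the same count adjusted over the list alone. Camera gave an adjusted p of 1.4e-24, and the call held with an estimated correlation (adjusted p = 0.0239 with an estimated correlation). Cd68 went from 0.573 ± 0.517 to 743 ± 41.6 CPM, Ptprc (CD45) from 6 reads, all in control replicate 1, to 168 ± 33.6 CPM, and Itgam (CD11b) from no read to 216 ± 45.9 CPM. Fcer1g had 1 read in the controls, in replicate 2, and 618 ± 80.9 CPM in the other group, and Tyrobp had 4 reads, all in control replicate 2, and 294 ± 42.7 CPM. The remaining 9 markers were not tested, among them the Kupffer cell genes Clec4f and Marco, which had no read in any library. Of the stellate cell and fibroblast markers only 2 were tested, and Acta2 passed at a low level (0.497 ± 0.351 and 2.06 ± 1.13 CPM). That call was lost without control replicate 1 (adjusted p = 0.0759 in edgeR), control replicate 3 (0.105) or replicate 1 labelled TXNIP overexpression (0.0877), with no filter (0.0541) and under the replicate block (0.0929). Without control replicate 2 its log2 fold change moved from 1.99 to 2.77. Of 4 tested endothelial markers, Egfl7 (7.45 ± 0.789 to 1.11 ± 0.348 CPM) and Flt1 (34.0 ± 2.66 to 17.8 ± 4.48 CPM) fell and 2 did not pass. Counts in both of these lists were the same adjusted over the list alone.

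**Figure D2:**
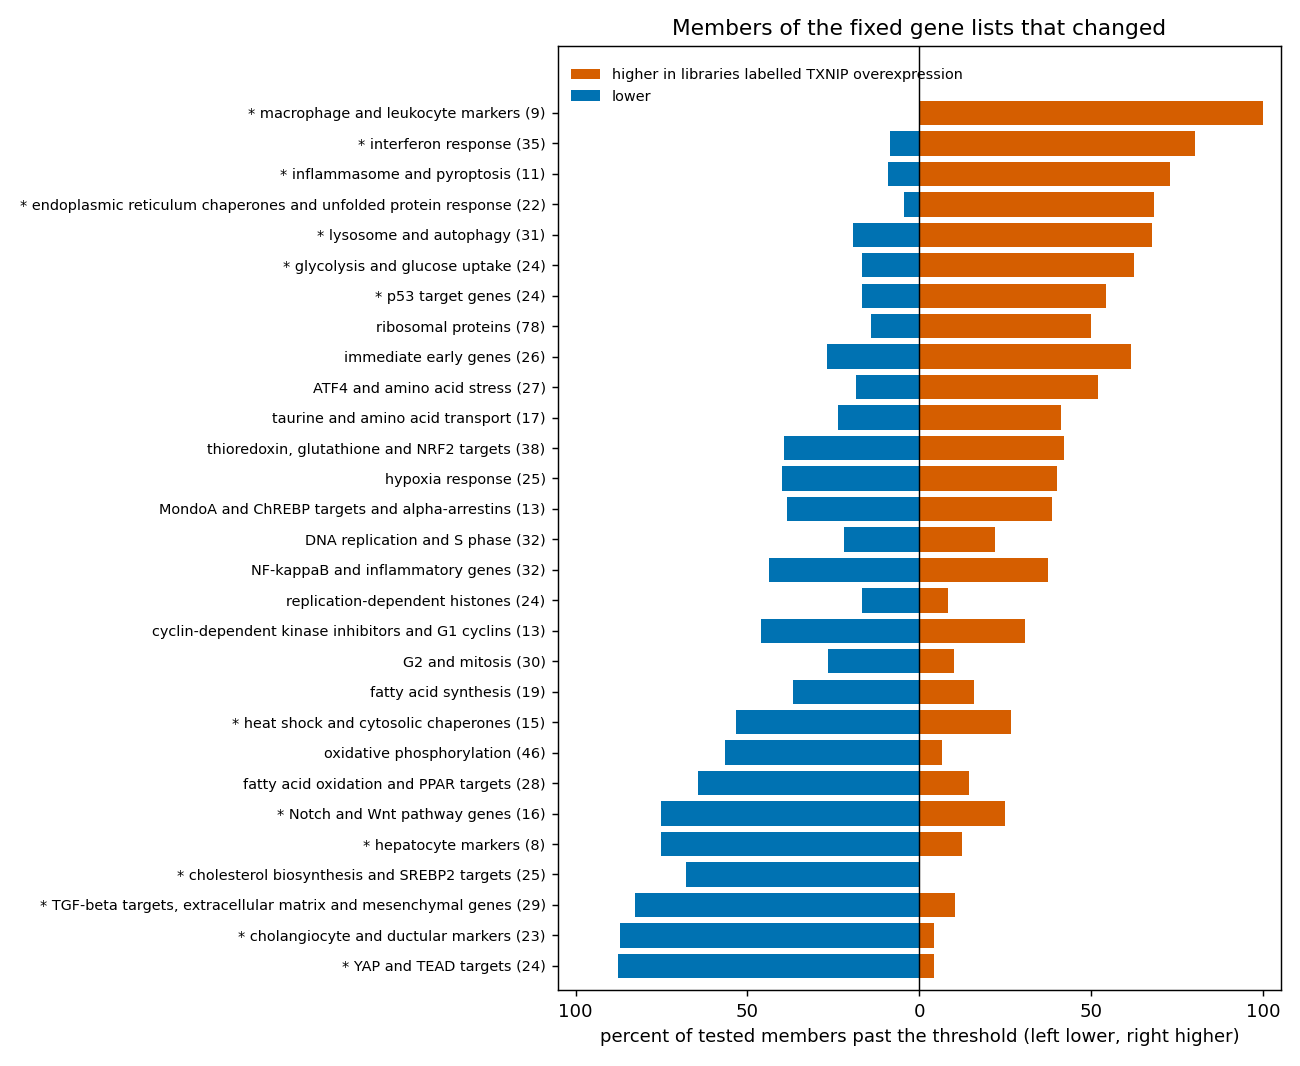
Percent of tested members of each fixed gene list that were higher (right, orange) or lower (left, blue) in the libraries labelled TXNIP overexpression, with the number of tested members in brackets and an asterisk where camera passed its threshold. All 9 leukocyte markers rose, and 20 of 23 ductular markers fell.

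In the libraries with leukocyte transcripts, of 29 tested TGF-beta targets, extracellular matrix and mesenchymal genes, 24 fell, 3 rose and 2 did not pass (camera adjusted p = 1.9e-16; adjusted p = 0.0452 with an estimated correlation). The counts were the same adjusted over the list alone. Sparc, a collagen-binding protein gene, went from 911 ± 41.1 to 0.350 ± 0.215 CPM, and the basement membrane gene Col4a1 from 288 ± 10.2 to 1.19 ± 0.251 CPM. Vim, Itga5 and Zeb2 rose, all of which macrophages also express. Of 24 tested YAP and TEAD targets, 21 fell, 1 rose and 2 did not pass, also adjusted over the list alone. Their camera call (adjusted p = 3.8e-16) was lost with an estimated correlation (adjusted p = 0.0549 with an estimated correlation). Ankrd1 fell from 945 ± 143 CPM to 3 reads, and Yap1, the coactivator gene itself, fell from 121 ± 6.30 CPM to 2 reads, both in replicate 1 labelled TXNIP overexpression. Notch and Wnt pathway genes fell in 12 of 16 cases and rose in 4, again the same adjusted over the list alone (camera adjusted p = 0.00549; adjusted p = 0.393 with an estimated correlation). Among genes with at least 5 CPM in both groups it did not pass (adjusted p = 0.848), but that restriction removes members near 0 in 1 group, such as Wnt7b, and so cannot count against the fall. Wnt7b went from 76.6 ± 13.1 CPM to no read, at least 760-fold lower, and Rbpj rose from 48.9 ± 3.78 to 330 ± 20.2 CPM.

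In the same libraries as the leukocyte markers, of 35 tested interferon response genes, 28 rose, 3 fell and 4 did not pass (28 and 4 adjusted over the list alone). The camera adjusted p was 2.7e-12 (adjusted p = 0.0866 with an estimated correlation). Rtp4 rose from 3.13 ± 1.40 to 133 ± 12.2 CPM, and Ifi44 had no read in the controls and 58.7 ± 5.04 CPM in the other group. The transcripts of the class I antigen presentation genes B2m (860 ± 17.3 and 739 ± 78.3 CPM) and H2-K1 (175 ± 4.39 and 143 ± 48.8 CPM) did not pass. Of 11 tested inflammasome genes, 8 rose, 1 fell and 2 did not pass, also adjusted over the list alone (camera adjusted p = 4.2e-04; adjusted p = 0.201 with an estimated correlation). Nlrp3 and Casp1, the sensor and the protease of the inflammasome to which TXNIP has been linked, had no read in the controls and 62.4 ± 19.4 and 38.0 ± 5.68 CPM in the other group. NF-kappaB and inflammatory genes went both ways, with 12 higher, 14 lower and 6 not past out of 32, also adjusted over the list alone (camera adjusted p = 0.48). Tnfaip2 rose from 30.1 ± 2.79 to 346 ± 20.6 CPM while Vcam1 fell from 132 ± 6.25 to 0.553 ± 0.327 CPM. Immediate early genes rose in 16 cases and fell in 7 of 26, the same adjusted over the list alone (camera adjusted p = 0.232). Jun rose from 33.7 ± 3.94 to 185 ± 13.4 CPM and Dusp6 fell from 186 ± 16.5 to 48.8 ± 6.19 CPM.

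In the libraries with high Csf1r and Cd14, of 31 tested lysosome and autophagy genes, 21 rose, 6 fell and 4 did not pass (21 and 8 adjusted over the list alone). The camera adjusted p was 0.0011 (adjusted p = 0.451 with an estimated correlation). The cathepsin gene Ctsb rose 12.5-fold, from 109 ± 4.86 to 1363 ± 185 CPM, and Gusb, a lysosomal glucuronidase gene, rose 13.2-fold. The autophagy genes Map1lc3b, Gabarapl1 and Wipi1 fell (log2 fold changes -1.96, -1.20 and -4.13). Of 22 endoplasmic reticulum chaperone and unfolded protein response genes, 15 rose, 1 fell and 6 did not pass, also adjusted over the list alone (camera adjusted p = 0.00739; adjusted p = 0.393 with an estimated correlation). Hspa5 (BiP) rose from 933 ± 71.9 to 2609 ± 226 CPM. Among 15 heat shock and cytosolic chaperone genes, 8 fell, 4 rose and 3 did not pass (8 and 5 adjusted over the list alone), with a camera adjusted p of 0.043 (adjusted p = 0.201 with an estimated correlation). Under the same restriction it did not pass (adjusted p = 0.41), with Hspb1 and Hspb8 removed by it. Hspa4l fell from 101 ± 12.8 to 14.2 ± 1.57 CPM and Stip1 from 324 ± 27.4 to 123 ± 7.04 CPM.

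Genes around glucose and the thioredoxin system moved in several directions, in the same libraries in which all 9 leukocyte markers rose. Arrdc4, an alpha-arrestin gene that responds to glucose as Txnip does, rose 8.45-fold, from 6.95 ± 3.86 to 58.7 ± 7.33 CPM. The MondoA and ChREBP target list as a whole had 5 higher, 5 lower and 3 not past of 13, also adjusted over the list alone (camera adjusted p = 0.85). ChREBP's own gene, Mlxipl, had 1.5 ± 0.181 CPM in the controls and no read in the other group, at least 14.9-fold lower. Of 24 tested glycolysis and glucose uptake genes, 15 rose, 4 fell and 5 did not pass, also adjusted over the list alone (camera adjusted p = 0.0434; adjusted p = 0.201 with an estimated correlation). The glucose transporter gene Slc2a1 rose 3.30-fold, from 60.2 ± 3.75 to 199 ± 14.2 CPM, and Pfkm fell from 45.5 ± 10.2 to 4.34 ± 1.99 CPM. The lactate exporter gene Slc16a3 rose 36.4-fold, from 5.95 ± 3.61 CPM in the controls, and its log2 fold change moved from 5.25 to 5.78 without control replicate 1. Thioredoxin itself (Txn1) had 914 ± 85.4 and 1071 ± 25.7 CPM and did not pass (edgeR adjusted p = 0.11). Txnrd1, the thioredoxin reductase gene, rose 1.95-fold. The thioredoxin, glutathione and NRF2 list had 16 higher, 15 lower and 7 not past of 38 (17 and 15 adjusted over the list alone; camera adjusted p = 0.875). In it the cystine transporter gene Slc7a11 rose 13.9-fold and Gstp1 fell 28.4-fold. The hypoxia list had 10 higher, 10 lower and 5 not past of 25 (11 and 10 adjusted over the list alone; camera adjusted p = 0.991), with Vegfa falling from 160 ± 5.09 to 31.2 ± 2.31 CPM.

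In the libraries in which all 9 leukocyte markers rose and 20 of 23 ductular markers fell, of 25 cholesterol biosynthesis genes, 17 fell, none rose and 8 did not pass, also adjusted over the list alone (camera adjusted p = 0.00739; adjusted p = 0.573 with an estimated correlation). Hmgcs1 fell from 474 ± 15.6 to 217 ± 16.3 CPM and Ebp from 502 ± 9.29 to 119 ± 24.0 CPM. Of 46 oxidative phosphorylation genes, 26 fell, 3 rose and 17 did not pass, also adjusted over the list alone, with a camera adjusted p of 0.191. Among genes with at least 5 CPM in both groups this list passed (adjusted p = 0.0146), with fewer genes to compare it with. Ndufv1 fell from 249 ± 31.3 to 89.0 ± 13.7 CPM. Fatty acid oxidation genes fell in 18 cases and rose in 4 of 28 (19 and 5 adjusted over the list alone; camera adjusted p = 0.232). Cd36, a fatty acid and scavenger receptor gene of macrophages, was among those that rose, with no control read and 46.8 ± 3.94 CPM. Fatty acid synthesis genes had 3 higher, 7 lower and 9 not past of 19, also adjusted over the list alone (camera adjusted p = 0.385), and Dgat1 was 3.33-fold lower. In the amino acid lists, 14 of 27 ATF4 and amino acid stress genes rose and 5 fell (15 and 5 adjusted over the list alone; camera adjusted p = 0.409). Of 17 taurine and amino acid transport genes 7 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.19). The taurine transporter gene Slc6a6 had 752 ± 176 and 586 ± 13.5 CPM, with a log2 fold change of -0.36 ± 0.15 and an edgeR adjusted p of 0.057. It passed under 5 alternatives, with adjusted p values from 0.0298 to 0.0461.

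The cell cycle lists did not pass camera, and single genes went both ways in the libraries with high leukocyte markers. Of 30 G2 and mitosis genes, 8 fell, 3 rose and 19 did not pass (6 and 3 adjusted over the list alone; camera adjusted p = 0.835). Of 32 DNA replication genes, 7 rose, 7 fell and 18 did not pass (5 and 5 adjusted over the list alone; camera adjusted p = 0.875). The proliferation marker Mki67 rose from 104 ± 7.53 to 306 ± 143 CPM, while Ccna2 fell from 286 ± 37.2 to 104 ± 5.82 CPM. Among 13 cyclin-dependent kinase inhibitors and G1 cyclins, 4 rose, 6 fell and 3 did not pass, also adjusted over the list alone (camera adjusted p = 0.193). Cdkn1a (p21) rose 14.1-fold, from 43.9 ± 1.15 to 621 ± 46.7 CPM. Cdkn2a, which encodes the inhibitors p16 and p19ARF, had 561 ± 17.3 CPM in the controls and 0, 1.06 and 0 CPM in the libraries labelled TXNIP overexpression. Its neighbour Cdkn2b had 21.6 ± 1.90 CPM and then no read, at least 214-fold lower. Ccnd1 (cyclin D1) had 1491 ± 163 and 1571 ± 80.1 CPM and did not pass (edgeR adjusted p = 0.61). Of 24 p53 target genes, 13 rose, 4 fell and 7 did not pass, also adjusted over the list alone, and Mdm2 rose from 49.8 ± 4.56 to 253 ± 27.5 CPM. Their camera call (adjusted p = 0.0434) was lost with an estimated correlation (adjusted p = 0.201 with an estimated correlation) under the stricter filter (0.0731) and under the replicate block (0.0586). It was also lost without control replicate 1 (0.0593), 2 (0.0649) or 3 (0.0509).

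The lists kept as checks of the libraries did not pass. Ribosomal protein genes had 39 higher, 11 lower and 28 not past of 78, also adjusted over the list alone (camera adjusted p = 0.153). Rps23 rose from 450 ± 31.2 to 1133 ± 68.6 CPM and Rps2 fell from 890 ± 116 to 100.1 ± 12.7 CPM, but ribosomal protein genes have many processed pseudogenes that can share their reads. Replication-dependent histone genes had 2 higher, 4 lower and 18 not past of 24 (1 and 0 adjusted over the list alone; camera adjusted p = 0.991). Median, mean and camera direction differed in sign for the histone, hypoxia, MondoA and NRF2 lists, none of which passed. In all, 14 of the 29 tested lists passed camera, 7 higher and 7 lower, and 3 of these held with an estimated correlation.

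Expression also differed by chromosome. Among genes with at least 10 CPM in both groups, the median log2 fold change relative to all such genes was 0.67 on chromosome 14, 0.62 on chromosome 12, -0.70 on chromosome 8, -0.67 on chromosome 19 and -0.47 on chromosome 15. Each had an adjusted permutation p of 1.8e-04, where 0.0001 is the smallest raw p that 10000 permutations can give. On chromosome 14, 82.8% of 221 genes lay above the median of all genes, and on chromosome 19, 17.8% of 297 did. Chromosomes 7 (0.31) and X (-0.30) lay closer. Of 20 chromosomes, 17 passed the permutation threshold, and genes along a chromosome are not independent, so the sizes say more than the p-values. Control replicate 1 against the other controls differed by at most 0.269 in size, on chromosome 7, and replicate 1 labelled TXNIP overexpression against the others of its group by at most 0.058, on chromosome 12.

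**Figure D3:**
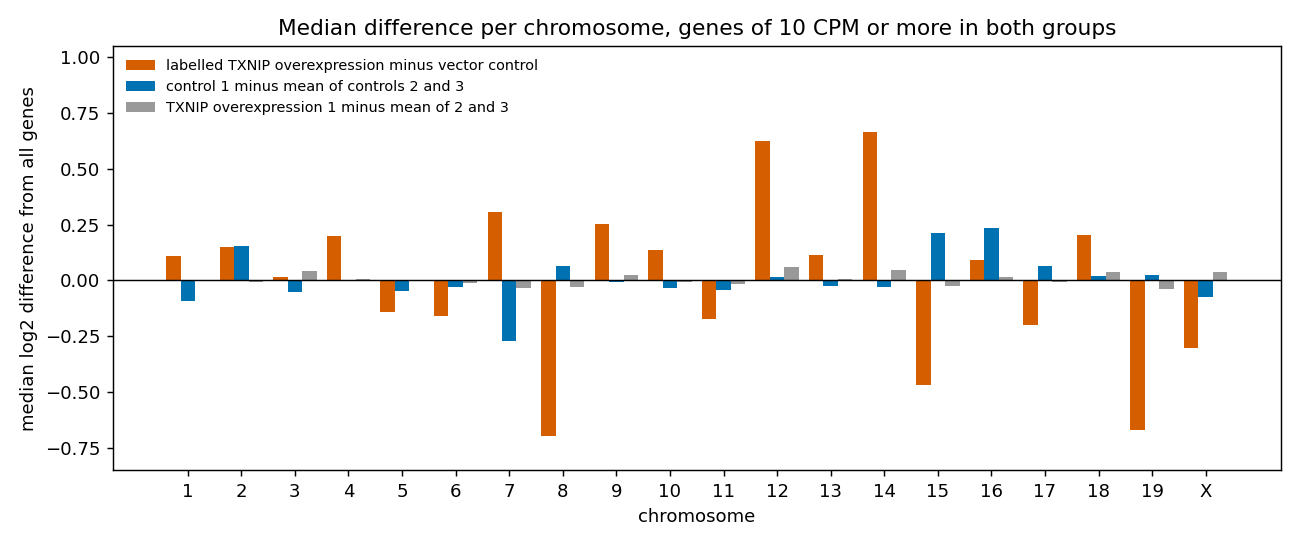
Median log2 difference of the genes on each chromosome from that of all genes, for the 7234 placed genes with at least 10 CPM in both groups. Orange bars compare the groups, blue bars control replicate 1 with the mean of the other controls, and grey bars replicate 1 with the mean of the others labelled TXNIP overexpression. Chromosomes 8 (-0.70), 19 (-0.67), 12 (0.62) and 14 (0.67) lay farthest from 0 between the groups.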

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

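The restriction to genes of at least 5 CPM in both groups and the removal of Rn45s were chosen after seeing the data. The count of changed genes stayed between 6440 and 8245 under 19 of the settings chosen beforehand and without Rn45s. A minimum fold of 1.5 gave 5301 changed genes, with 2382 higher and 2919 lower. Restriction to genes of at least 5 CPM in both groups gave 5021, with 2583 higher and 2438 lower, with 8425 genes tested. Leaving out 1 library at a time gave 7201 to 7870 changed genes. Txnip passed under every alternative run, with log2 fold changes from 3.48 to 4.71, the highest without control replicate 1. Of the 7796 calls, 7757 were also made by DESeq2 and 7675 by limma-voom. The median log2 fold change of all genes was -0.04 with TMM factors and -0.11 with library size alone, and the share of higher calls moved from 47.4% to 44.1%. The lists past the threshold numbered 14 by camera, 3 with an estimated correlation and 23 by fry. With 1 library left out they numbered 12 to 14. Among genes of at least 5 CPM in both groups they numbered 9 of 25, because 4 of the 14 (ductular, hepatocyte, leukocyte and inflammasome) kept too few members to test, 2 lost the call and 1 gained it. For fry the cause lies in the test itself, since fry does not compare a list with other genes. For the estimated correlation the cause was not tested. The p53, glycolysis and heat shock lists lost their calls at estimated correlations of -0.005, -0.011 and -0.015, below the preset of 0.01. A higher correlation among their genes therefore cannot be the cause for them. All 14 lists called by camera also passed fry in the same direction. Of 2443 values of named genes under alternatives, 2422 kept direction and call, 14 lost the call (Acta2, Hist1h2an, Hist1h2ae and Hist1h2af), 5 gained it (Slc6a6) and 2 changed sign. With 1 library left out, Alb ranged from -3.80 (without replicate 3 labelled TXNIP overexpression) to 0.23 (without control replicate 3, adjusted p = 0.893 in edgeR). Ccnd1 ranged from -0.016 (without control replicate 1, adjusted p = 0.901 in edgeR) to 0.126 (without control replicate 3). Neither gene had passed, and the cause was not tested. The labels give no pairing by replicate number. Deviations of same-numbered libraries correlated across genes at 0.0666, 0.0215 and 0.0351 over all genes, and at 0.128, 0.0713 and 0.0467 over genes of at least 20 CPM. Not every library matched its own number best, and a batch shared by number stays open. With the replicate number as a block, 7767 genes changed and 13 lists passed. Thinning to the smallest total left 7617 changed genes.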

Other observations

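The tests on mixing, on exchanged libraries, on a batch shared by number, on the karyotype of control replicate 1 and on pairs of genes were chosen only after the result was seen, as were the lists of transcription factors. The tests on chromosomes between the groups and on depth were prompted by patterns already seen, but their bounds were written before those values were computed. The bounds for the karyotype of control replicate 1 and the limits that define equal pairs were set with the values in view.

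The lists of transcription factors were written with the data in view and were not tested as lists, so their counts are no independent evidence. Of 16 tested myeloid transcription factors and receptors, 11 were higher and 2 lower in the libraries labelled TXNIP overexpression. Spi1 (PU.1), which drives macrophage development, had 1.40 ± 0.318 CPM in the controls and 377 ± 14.6 CPM in the other group, and Irf8 and Ikzf1 had no control read and 52.6 ± 1.54 and 47.3 ± 4.51 CPM. Maf and Csf1r are in the same list, and Maf went the other way, from 28.4 ± 2.50 CPM to 1 read. Of 16 liver and epithelial transcription factors, 15 were lower and none higher, with Foxa1 at 24.3 ± 1.13 CPM in the controls and no read in the other group. Of 8 kidney and other mesoderm factors, 7 were lower and none higher. Pax2, a factor of the kidney and genital tract, had 143 ± 2.11 CPM in the controls and no read in the other group.

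Several single genes stood out after their values were seen. The Y-linked gene Ddx3y had 14.4, 0.762 and 1.31 CPM in the controls and 96.6, 84.8 and 71.7 CPM in the libraries labelled TXNIP overexpression. The Y-linked genes Eif2s3y, Kdm5d and Uty also rose, from means of 0.571, 0.918 and 1.03 CPM to 28.6, 10.6 and 7.13 CPM. Control replicate 1 was the highest control for each. The 3 controls had 1.10, 0.416 and 0.196 CPM of Eif2s3y, 2.20, 0.554 and 0 CPM of Kdm5d, and 3.08, 0 and 0 CPM of Uty. Xist had no read in any library. At the locus of Cdkn2a and Cdkn2b on chromosome 4, the neighbouring gene Mtap kept 96.9, 83.1 and 102 CPM in the libraries labelled TXNIP overexpression, against 148, 158 and 142 CPM in the controls. The 11 Cdkn2a reads of that group all came from its replicate 2. S100a6 had 8316 ± 736 CPM in the controls and 1184 ± 36.8 in the other group, and S100a4 went the other way, from 72.7 ± 4.45 to 4480.3 ± 366 CPM.

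Leukocyte genes were high and epithelial genes near 0 in all 3 libraries labelled TXNIP overexpression. Macrophages mixed into a culture that kept its epithelial cells are argued against. In any of those libraries, 17 ductular markers with at least 20 CPM in the controls kept a median of at most 0.0343% of that level. A culture wholly taken over by macrophages was not tested, and this bound was set after the pattern was seen. The summed level of these ductular markers was 85.2%, 110.3% and 120.1% of the control mean, against 120.0%, 90.5% and 89.5% in the single controls. Only in replicate 1 did it lie below every control. The sum includes Spp1, which rose and is also expressed by macrophages. Anxa4, Slc4a2 and Pkd2 kept 99.4, 56.7 and 23.6 CPM. An exchange of single libraries between the groups is also argued against, because 8 abundant leukocyte markers stood at a median of at most 0.0740% of the other group's level in any control. Csf1r and Cd14 were less low, with means of 28.0 and 53.4 CPM in the controls. An exchange of the labels of both whole groups cannot be seen in this way and was not tested. A culture with another karyotype, such as a different cell line, is a candidate explanation, since 7 chromosomes had medians more than 0.3 from that of all genes, where the explanation needed at least 3. Chromosomes 7 (0.306) and X (-0.301) only just passed that bound. On chromosome 7 control replicate 1 also lay -0.269 from the other controls. As 17 of 20 chromosomes passed the permutation threshold, the karyotype explanation rests on the size of the medians. Differences in gene regulation between chromosomes were not separated from copy number. An effect of TXNIP on cell identity was not tested and stays open, as does a mix-up with samples from outside the series. The label and the cell-type profile are the same split of the libraries. An effect of TXNIP would also have to account for the chromosome medians and for the Y-linked transcripts. Among the controls, Ddx3y and Eif2s3y were low in every library and highest in replicate 1. Kdm5d had no read in control replicate 3, and Uty had none in control replicates 2 and 3. Of the 10 ways to split the 6 libraries into 3 and 3, only the real one gave as many as 7796 changed genes. The highest of the others gave 0, but those splits mix the groups on both sides, which widens the spread. Their 0 calls therefore decide nothing, and 10 splits are too few for a share under 0.05.

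Control replicate 1 stood apart from the other controls, with 106 of 6921 genes over 2-fold from their mean. Control replicates 2 and 3 had 31 and 30 such genes. Replicate 1 labelled TXNIP overexpression differed that much from the mean of the others of its group in 63 of 6580 genes. Thinning all controls to the smallest total, that of control replicate 1, left 110 genes over 2-fold. Thinning leaves the counts of control replicate 1 unchanged and so could not lower their counting error. It did bring control replicates 2 and 3 down to that depth, and the number moved only from 106 to 110. Of the 106 genes, 78 were higher in control replicate 1, while counting error would not favour 1 direction. These values argue against lower depth as the cause for these genes, which had a mean of at least 20 CPM in the controls. A subculture with another karyotype stays open, since its bounds were set with the values in view and so decide nothing. The Y-linked gene Ddx3y was also higher in control replicate 1, at 14.4 CPM against 0.762 and 1.31 CPM in the other controls. The largest chromosome median of control replicate 1 lay 0.269 away from that of all genes, on chromosome 7, and 11 chromosomes passed the permutation threshold against 0 for replicate 1 labelled TXNIP overexpression. A batch shared by the libraries numbered 1 stays open, since their deviations correlated at 0.128 across genes, between the bounds of 0.1 and 0.3. Those bounds were set after the result was seen, and no chance level was computed. No biological explanation was tested for this pattern.

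In 9 pairs of genes with at least 3000 reads, the counts of both members agreed within 2% in every library. The positions of 4 pairs overlapped (44.4%): Rplp2-ps1 with Wdr89, Snx22 with Ppib, Htra2 with Loxl3 and Foxp3 with Ccdc22. For these, reads at 1 locus counted for both genes are a candidate explanation, so the level of Foxp3, a regulatory T cell gene, may be that of Ccdc22. The other 5 pairs do not overlap, among them Atp6v0c with its pseudogene Atp6v0c-ps2, which argues against overlap for them, and reads shared between similar copies were not tested. No biological explanation was tested.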
